A study of Mus musculus with 6 samples.

How the data were processed

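The series holds 6 RNA-seq libraries of antrum epithelium, the lining of the distal stomach, from C57BL/6 mice with atrophic gastritis. Per the labels' protocols, gastritis was induced with MNNG, an alkylating carcinogen, together with a drug written as Ranitine, over 20 weeks. PEEPA-P5 was then given by gavage for 2 weeks, and the comparison animals received vehicle. PEEPA-P5 is known here only by that code name. Each group has 3 libraries. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, frozen epithelium was extracted with Trizol, and libraries were made from total RNA with an Illumina TruSeq kit. Whether the libraries kept the strand is not given in the sources used here, so genes overlapping on opposite strands cannot be told apart.

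Per the submitters' processing notes, the authors used Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm9. The roles and settings of these tools are not given in the sources used here. Per the file headers, the authors deposited for each library an expected count, an FPKM value and a TPM value for 17256 genes, with Entrez identifiers and symbols. The deposited expected counts are RSEM estimates of reads per gene, not normalized, and 9.82% of them were not whole numbers. They were rounded to whole numbers before testing. FPKM is scaled by the authors to library size and transcript length, and TPM by the authors to a fixed sum per library. The authors' group mean columns were not used for tests. Of the identifiers, 17206 matched a mouse RefSeq gene table of assembly GRCm38.p6, which served for older symbols only. No coordinates are printed, because the reference used here is a later build than mm9.

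Total counts per library ran from 16388844 to 16903545. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 13.3 over genes with 20 or more counts in the pair, so no library was taken as a duplicate. Intervals and tests on these reads treat them as molecules although no molecular identifiers are described.

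The comparison was PEEPA-P5 against vehicle, without covariates. Counts were tested with edgeR 4.0.16 in R 4.3.3 by its robust quasi-likelihood test, with TMM factors and edgeR's expression filter, which left 13071 genes. The p-values were adjusted by the Benjamini-Hochberg method at 0.05. Log2 fold changes and their standard errors come from that fit, and CPM values use the TMM-scaled library sizes. Before the data were examined, 49 gene lists for cell types and pathways, with 1434 memberships in all, were written down, of which 1353 were in the table. The 46 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment. Camera with an estimated correlation and fry were run beside it. A list's median is the median over its members of the difference in mean log2 CPM. The mean log2 CPM of each list per library was compared by an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

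The genes named in the text follow a rule fixed at the same time. It takes up to 12 genes per direction with the largest fold change among those that pass the adjusted threshold, reach 1 CPM in the higher group and do not overlap between groups. Where none passes, it takes the 6 with the smallest unadjusted p in each direction, under the same conditions on CPM and overlap. It adds up to 4 members of each list that passes, and a set of antral, oxyntic and intestinal products. Predicted gene models were counted but not named, and a further gene that the rule takes is not reported here. The share of the named genes' 31-base stretches that also occur in transcripts of other genes was counted in the GENCODE M21 transcripts, to mark genes whose reads RSEM would have had to divide.

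The labels number the libraries of both groups 1 to 3 without saying what a number means. Over all tested genes, deviations from the group means correlated at 0.237, 0.346 and 0.235 for libraries 1, 2 and 3 of both groups, and each library correlated best with its own number. As every same-numbered pair correlated above 0.1, the numbers were taken as possible pairs. Vehicle 2 and PEEPA-P5 1, of unlike number, also correlated above 0.1, at 0.176. The main fits and the exact permutation tests took the libraries as unpaired, so their p-values, the smallest possible included, leave such pairs out of account. This pairing comes from the data and not from the labels, so like directions in the numbered pairs are not independent support. A fit with the number as a block is given wherever it changed a call.

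The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other count filters, limma-trend on log2 TPM with pseudocounts of 1 and 0.1, the replicate block, and each library left out in turn. Added after the data had been seen were a fit without both libraries numbered 3, DESeq2 with the replicate block, and blocked set tests with an estimated correlation or fry. The test was tried on simulated counts with this comparison's library sizes and means, over 12894 tested genes. It called 8% of genes changed 1.5-fold, 32% of those changed 2-fold, 86% of those changed 4-fold and 85.4% of those changed 8-fold. Of 112 calls, 8 were false. Camera called a simulated list shifted 2-fold and 0 of 44 other lists, over 12887 genes. Genes were independent in the simulation, so it does not test the preset correlation where genes vary together. Figures were drawn with matplotlib.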

Results

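RNA was sequenced from the antrum epithelium of mice with induced atrophic gastritis, after 20 weeks of MNNG and Ranitine. Of the 6 libraries, 3 came from animals then given vehicle for 2 weeks and 3 from animals given PEEPA-P5 for 2 weeks. Total counts were 16833280, 16808834 and 16388844 in vehicle 1, 2 and 3 and 16533650, 16903545 and 16494792 in PEEPA-P5 1, 2 and 3. The question of the design is which transcripts differ between gastritis mice with and without PEEPA-P5. Tff1, a secreted trefoil peptide of gastric surface cells, took 4.45% to 6.71% of the counts of a library.

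No single gene passed the adjusted threshold. The genes with the smallest p-values in each direction, among those that the naming rule allows, are described first. Krt78 (Entrez 332131), a keratin, stood at 53.8 ± 5.19 CPM with PEEPA-P5 against 23.7 ± 3.61 CPM with vehicle (SD, n = 3 each), a log2 difference of 1.18 with a standard error of 0.14. Slurp1 (Entrez 57277), a secreted Ly6-family protein of stratified epithelia, was at 184 ± 8.12 against 93.3 ± 23.2 CPM. S100g (Entrez 12309), the calcium-binding protein calbindin-D9k, was at 25.5 ± 6.02 against 10.04 ± 2.15 CPM, and the phospholipase gene Pla2g4e at 14.4 ± 4.22 against 4.96 ± 0.82 CPM. A further keratin, Krt79, was at 35.96 ± 1.24 against 20.6 ± 3.66 CPM. In the other direction, H6pd (Entrez 100198), which makes NADPH in the endoplasmic reticulum, was at 45.4 ± 1.44 CPM with PEEPA-P5 against 69.7 ± 5.84 CPM. Capn6, a calpain-family gene, was at 9.05 ± 0.82 against 17.3 ± 2.03 CPM, the histone deacetylase gene Hdac11 at 17.1 ± 0.36 against 28.0 ± 4.17 CPM, and Ceacam10 at 1.37 ± 0.29 against 4.74 ± 1.32 CPM. In each of these genes every PEEPA-P5 library lay on one side of every vehicle library, which the naming rule required.

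Of 13071 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.412. At an unadjusted p under 0.05 there were 774 higher and 802 lower genes, 1576 in all, where chance alone gives about 654. The groups did not overlap in 2672 genes, or 20.4%, against 10% by chance. Both chance values take the libraries as independent and unpaired. Other splits of the 6 libraries gave from 90 to 1092 genes at an unadjusted p under 0.05. Limma-voom also called 0 genes, whereas DESeq2 called 110, of which 39 were higher and 71 lower. Among the 12 genes named by smallest p, DESeq2 called 12, but they were picked from the same counts, so this is no independent check. The count at an unadjusted p under 0.05 was 717 without vehicle 2, 759 without vehicle 3 and 1008 without PEEPA-P5 1. Without vehicle 1, edgeR called 1 gene past the adjusted threshold, the predicted gene Gm42048, which was chosen for mention after its values were seen, at a log2 difference of 5.29 against 1.98 over all 6 libraries.

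Of those 12 genes, Entpd4, Srp54b and Pcdhgb1 share sequence with near copies and are uncertain. Their copies are named here after their values were seen. Entpd4 had 0 counts in all vehicle libraries and 4.43 ± 1.81 CPM with PEEPA-P5, but its annotated transcripts share 100% of their sequence with Entpd4b. Entpd4 and Entpd4b together were at 59.6 ± 26.7 CPM with PEEPA-P5 and 62.7 ± 16.8 CPM with vehicle (exact permutation p = 0.9, two-sided). Srp54b was at 34.5 ± 3.91 against 53.6 ± 3.37 CPM, and shares 86.1% of its sequence with Srp54a, which was at 64.5 ± 3.43 against 50.4 ± 6.60 CPM. Pcdhgb1 had 0 counts in all PEEPA-P5 libraries and 1.13 ± 0.52 CPM with vehicle, and 63.9% of its sequence occurs in transcripts of other genes, with 53.9% in Pcdhga4.

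**Figure D1:**
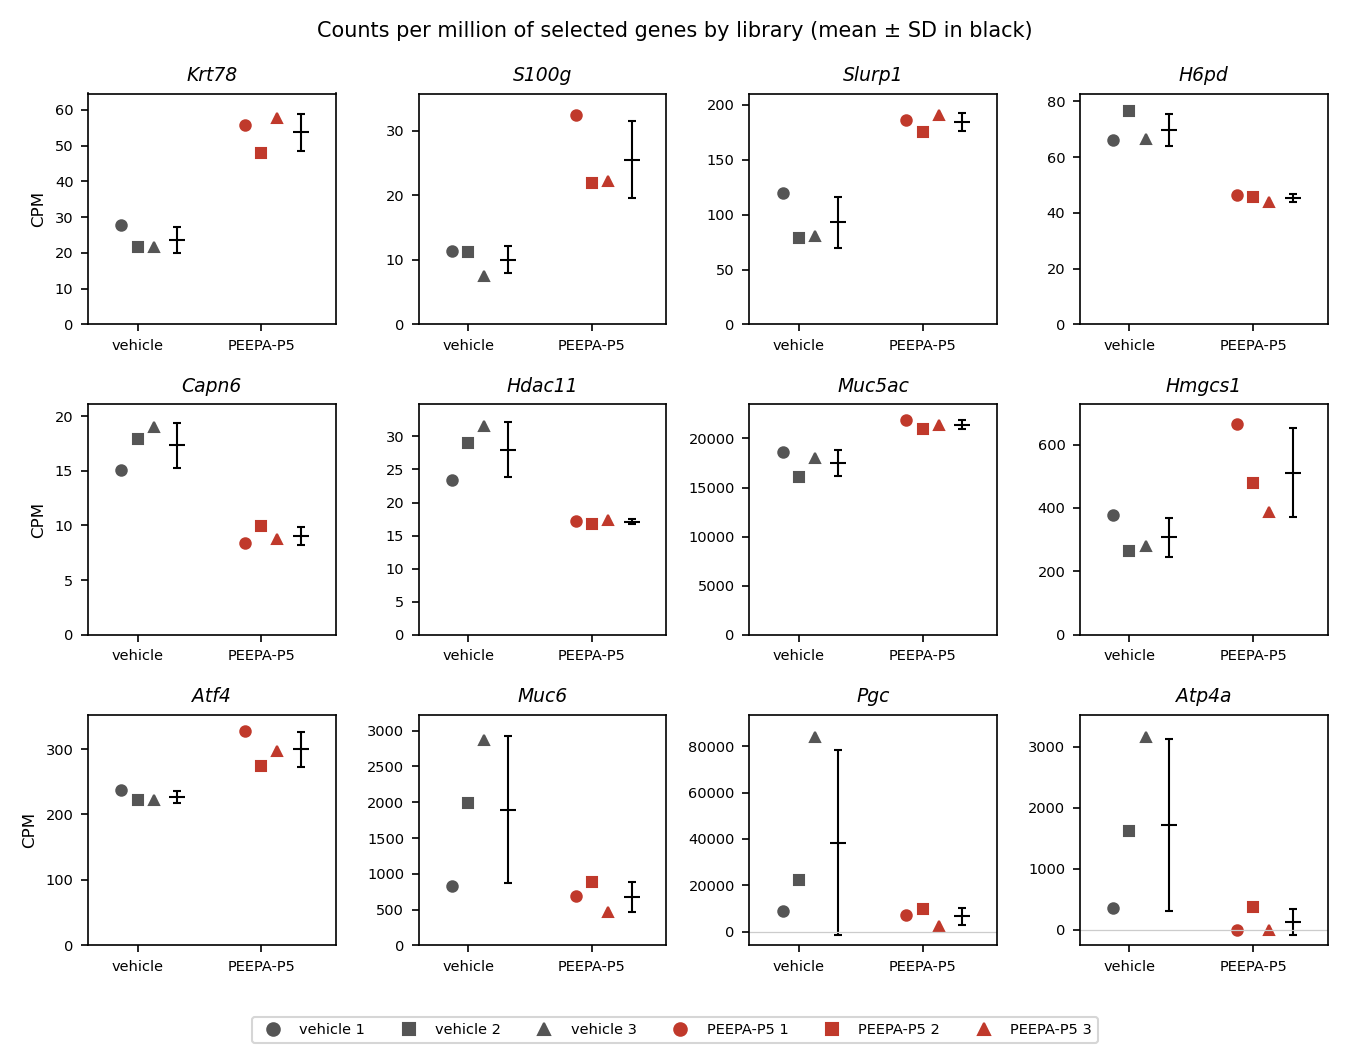
CPM (vertical axes, linear) of 12 genes named in the text, none past the adjusted threshold, in each library of the vehicle (grey) and PEEPA-P5 (red) groups, with the library number as the marker shape and mean ± SD of 3 libraries in black. Krt78 sits between 47.9 and 57.8 CPM with PEEPA-P5 and between 21.6 and 27.8 CPM with vehicle, while Pgc runs from 9021 to 84030 CPM within the vehicle group alone.

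Of the fixed gene lists, 15 of the 46 tested passed camera with its preset correlation, 7 of them rising and 8 falling with PEEPA-P5. With an estimated correlation 0 of the 46 passed, and the smallest adjusted p was 0.796. Fry called 0 lists in either form. With camera's preset correlation, 6 of the 10 splits of the libraries into 3 and 3 called at least 15 lists, the real one included. The highest other split called 20. For each of the 15 lists the adjusted p with an estimated correlation, at which every call is lost, is given beside the one with the preset correlation, and the list means per library were compared by an exact two-sided permutation test (n = 3 each). No member of any list passed the threshold over all genes. With each library left out in turn, 8 of the 15 lists kept their call every time, and the number of lists that passed was 24 without vehicle 3 and 23 without PEEPA-P5 2.

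The genes of cholesterol and fatty acid synthesis rose, with 34 of 36 tested members higher and a median log2 difference of 0.33 (camera adjusted p 4.1e-06, adjusted p = 0.814 with an estimated correlation). Of these members, 12 were higher at an unadjusted p under 0.05 and 0 lower, and 0 passed when adjusted over the list alone. Hmgcs1, which forms the HMG-CoA that enters sterol synthesis, was at 511 ± 141 CPM with PEEPA-P5 against 308 ± 61.5 CPM with vehicle. Mvd, a decarboxylase of the mevalonate pathway, was at 45.8 ± 16.2 against 25.3 ± 4.09 CPM. Idi1, the isopentenyl isomerase, which shares 18.8% of its sequence with other genes, was at 150 ± 29.7 against 96.6 ± 17.6 CPM, and Cyp51, the lanosterol demethylase, at 221 ± 25.8 against 160 ± 12.1 CPM. The exact permutation test of the list means gave p = 0.2 (two-sided, n = 3 each), as PEEPA-P5 3 lay within the vehicle range, and the list mean was higher with PEEPA-P5 in 3 of 3 numbered pairs. With each library left out in turn the list's median stayed between 0.25 and 0.49.

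The list written for squamous epithelium of the forestomach rose, with 11 of 12 tested members higher and a median log2 difference of 0.74 (camera adjusted p 2.1e-05, adjusted p = 0.796 with an estimated correlation). Adjusted over the list alone, 5 members passed. S100a14, an epithelial S100 protein, was at 216 ± 27.1 CPM with PEEPA-P5 against 120 ± 21.4 CPM. Serpinb5, an epithelial serpin, was at 73.7 ± 16.9 against 48.5 ± 7.04 CPM, and Krt13 at 7.91 ± 3.68 against 2.40 ± 1.09 CPM. Rptn, a cornified-envelope gene, was at 1.53 ± 0.54 against 0.56 ± 0.04 CPM. Krt5 and Krt14, the basal keratins of squamous epithelium, had at most 1 count in any library and are named here after their values were seen. The list means of all PEEPA-P5 libraries lay above those of all vehicle libraries (exact permutation p = 0.1, two-sided, the smallest possible). The highest mean was that of PEEPA-P5 3, at 0.58 log2 units above the mean of the 6 libraries, the library with the lowest endothelial and fibroblast means. Without PEEPA-P5 3 the median was 0.47, and the list still passed.

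Surface mucous (pit) cell genes rose by a smaller amount, with 14 of 17 members higher and a median log2 difference of 0.30 (camera adjusted p 0.0015, adjusted p = 0.814 with an estimated correlation). Muc5ac, the main gel-forming mucin of the gastric surface, was at 21400 ± 480 CPM with PEEPA-P5 against 17530 ± 1321 CPM with vehicle, with a log2 difference of 0.29 and a standard error of 0.11 (edgeR adjusted p 0.412). Gkn1 was at 29740 ± 3127 against 23970 ± 2161 CPM, and Gkn2 at 37970 ± 3738 against 31790 ± 1810 CPM. In the same list Tff1 was at 60530 ± 12100 against 47410 ± 6196 CPM, and Mucl3, Capn8, Anxa10 and Tspan8 had log2 differences of 0.40, 0.43, 0.42 and 0.33. The pit list means did not overlap between groups (exact permutation p = 0.1), but PEEPA-P5 1 and 2, at -0.02 and -0.01 log2 units from the mean of the 6 libraries, lay close to vehicle 1 at -0.03. Without PEEPA-P5 3 the median was 0.18, and the list still passed. Epithelial junction and keratin genes also rose, with 28 of 33 members higher and a median of 0.27 (camera adjusted p 2.1e-05, adjusted p = 0.814 with an estimated correlation). Among them Krt20, a keratin of mature surface cells, was at 1088 ± 249 against 594 ± 192 CPM, Krt19 at 7464 ± 665 against 5487 ± 892 CPM, and the tight-junction gene Cldn7 at 22.8 ± 6.15 against 12.01 ± 2.73 CPM. The desmosomal gene Dsc2 was at 441 ± 93.6 against 296 ± 37.6 CPM. The junction list mean was highest in PEEPA-P5 3, at 0.41 against -0.06 and 0.10 in PEEPA-P5 1 and 2 (exact permutation p = 0.2), and PEEPA-P5 3 was also the library with the lowest means for endothelium (-1.94), fibroblasts (-2.15) and smooth muscle (-1.78). The pit list too had its highest mean there, at 0.39. Without PEEPA-P5 3 the junction median was 0.16, and without both libraries numbered 3, left out after the data had been seen, it was 0.08 and the list no longer passed. In the lists of pit and junction genes 0 members passed when adjusted over the list alone.

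Genes of the unfolded protein response rose slightly, with 26 of 35 members higher and a median log2 difference of 0.15 (camera adjusted p 0.0059, adjusted p = 0.796 with an estimated correlation). The stress-response transcription factor genes Atf4 and Atf3 were at 300 ± 26.9 against 227 ± 8.80 CPM and at 41.9 ± 11.6 against 23.5 ± 3.90 CPM. The chaperone gene Dnajb11 was at 106 ± 5.44 against 85.7 ± 4.74 CPM, whereas Derl3, a degradation factor of secretory cells, was at 0.37 ± 0.10 against 2.02 ± 1.54 CPM. The list means overlapped (exact permutation p = 0.3), with PEEPA-P5 3 at -0.05 below vehicle 2 and vehicle 3, and 2 of 3 numbered pairs were higher with PEEPA-P5. Without vehicle 1 the list no longer passed, at a median of 0.13. Apoptosis genes rose, with 22 of 33 members higher and a median of 0.22 (camera adjusted p 0.0175, adjusted p = 0.814 with an estimated correlation). Members known to act in opposite directions were among them, such as Bcl2l1, which restrains apoptosis, at 101 ± 16.5 against 76.9 ± 9.08 CPM, and Bok, which promotes it, at 42.5 ± 2.48 against 35.7 ± 2.03 CPM. Casp8 and Mlkl, which act in apoptosis and necroptosis, had log2 differences of 0.27 and 0.40. The highest apoptosis list mean was that of vehicle 1, at 0.16 against 0.04, 0.09 and 0.09 with PEEPA-P5 (exact permutation p = 0.4), and 2 of 3 numbered pairs were higher with PEEPA-P5. The apoptosis call was lost without vehicle 2, at a median of 0.12, and without vehicle 3, at a median of 0.15, and without PEEPA-P5 3 the median was 0.13.

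Parietal cell genes fell, with 15 of 17 members lower and a median log2 difference of -2.35 (camera adjusted p 2.1e-05, adjusted p = 0.814 with an estimated correlation). Chief cell genes fell, with 5 of 5 members lower and a median of -2.14 (camera adjusted p 0.0044, adjusted p = 0.814 with an estimated correlation). Atp4a, the catalytic subunit of the gastric proton pump, was at 130 ± 220 CPM with PEEPA-P5 against 1717 ± 1403 CPM with vehicle, a log2 difference of -3.73 with a standard error of 2.16. Its partner Atp4b was at 84.2 ± 141 against 1347 ± 1255 CPM. The channel genes Kcnq1 and Kcnj15 were at 23.8 ± 8.84 against 59.1 ± 26.7 CPM and at 84.1 ± 12.99 against 221 ± 126 CPM. Slc26a7 was at 0.36 ± 0.36 against 7.68 ± 8.52 CPM, and Clic6 at 38.6 ± 26.6 against 208 ± 164 CPM. Pgc, the precursor of pepsin C, was at 6654 ± 3611 against 38470 ± 40020 CPM. Cblif, which encodes gastric intrinsic factor, was at 80.3 ± 70.9 against 400 ± 141 CPM, and Pga5 and Bhlha15 had log2 differences of -1.34 and -1.22.

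These genes differed widely between libraries of the vehicle group. Pgc took 0.932%, 2.47% and 8.01% of the counts of vehicle 1, 2 and 3, and 0.751%, 0.991% and 0.244% in PEEPA-P5 1, 2 and 3. The means of the parietal and of the chief list in every PEEPA-P5 library lay below those in every vehicle library (exact permutation p = 0.1 for each, two-sided, the smallest possible), but PEEPA-P5 2 and vehicle 1 were close, at 0.23 and 0.24 log2 units above the parietal mean of the 6 libraries. PEEPA-P5 3 was the lowest library for both lists, at -2.40 for parietal and -3.03 for chief cells, and also had the lowest means for exocrine pancreas (-2.71), enteroendocrine cells (-2.33), fibroblasts (-2.15) and endothelium (-1.94). Without vehicle 3 the chief median was -1.29, and without both libraries numbered 3 it was -0.73 and the parietal median -1.12. Muc6, the mucin of antral glands and neck cells, was at 679 ± 211 against 1896 ± 1024 CPM. The list of gland and neck mucous cells, which also holds Pgc, did not pass as a whole (camera adjusted p 0.261). Its member Tff2 was at 6779 ± 249 against 6152 ± 747 CPM.

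Genes of the list for exocrine pancreas fell too, with 10 of 12 members lower and a median log2 difference of -3.51 (camera adjusted p 0.0015, adjusted p = 0.814 with an estimated correlation). The lipase genes Cel and Pnliprp2 were at 0.63 ± 0.84 against 8.88 ± 5.79 CPM and at 11.1 ± 5.13 against 41.6 ± 21.6 CPM. The amylase gene Amy2a5 was at 4.96 ± 8.60 against 591 ± 507 CPM, but shares 62% of its sequence with Amy2a2. The major pancreatic protease genes Prss1, Ctrb1 and Cela3b had at most 3, 2 and 2 counts in any library and are named here after their values were seen. The member Zg16 also stands in the intestinal list. The list means overlapped, with PEEPA-P5 2 above vehicle 1 (exact permutation p = 0.2), and 3 of 3 numbered pairs were lower with PEEPA-P5. Without both libraries numbered 3 the pancreas median was -1.91 and no longer passed, and without PEEPA-P5 1 or PEEPA-P5 3 it was -2.27 or -2.28 and passed.

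**Figure D2:**
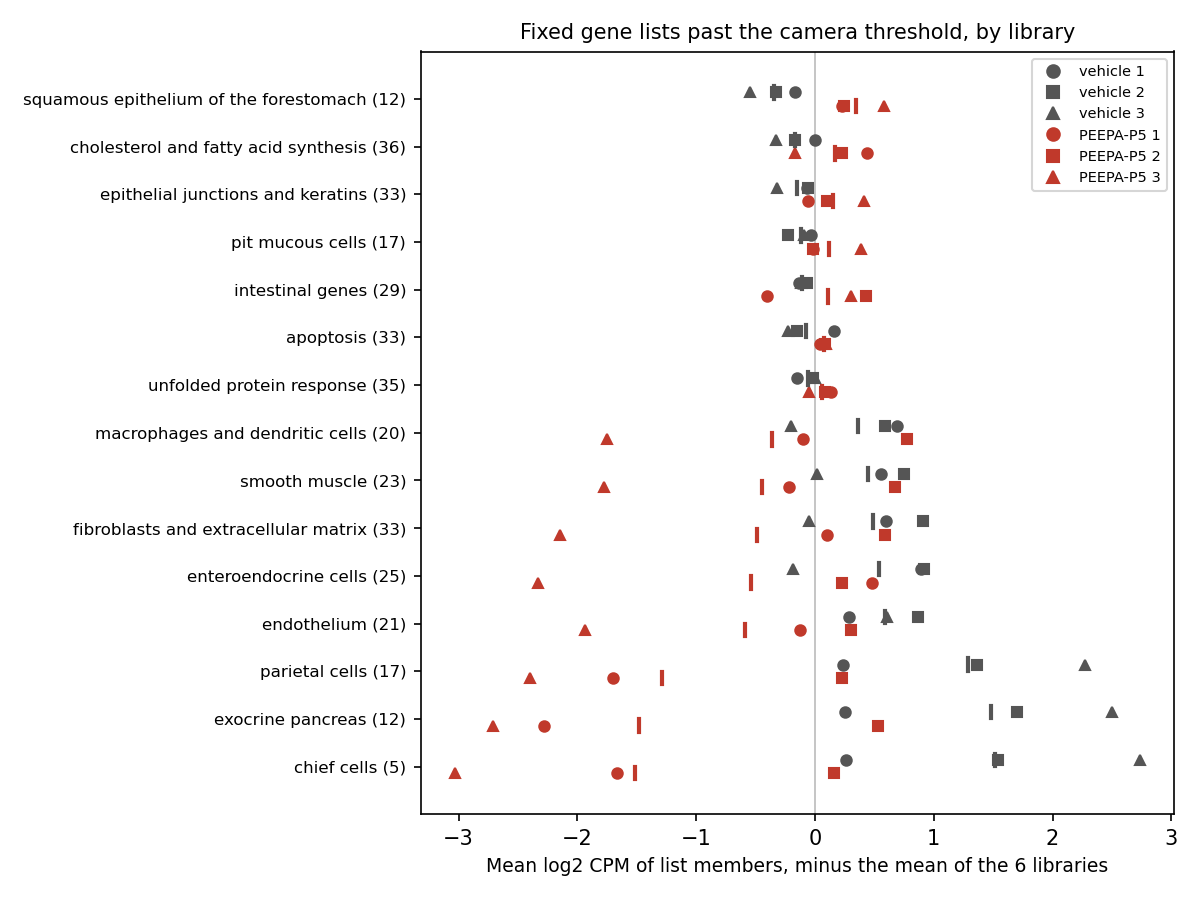
Mean log2 CPM of the members of each of the 15 lists that passed camera with its preset correlation, per library, minus the mean over the 6 libraries (horizontal axis, log2 units), with the number of tested members in brackets, libraries as points and group means as short bars. PEEPA-P5 3 lies at -1.94 for endothelium and -2.15 for fibroblasts, while vehicle 3 lies at 2.27 for parietal cells.

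Intestinal genes rose, with 22 of 29 members higher and a median log2 difference of 0.51 (camera adjusted p 0.018, adjusted p = 0.814 with an estimated correlation). Zg16, a lectin secreted by goblet cells, was at 424 ± 194 CPM with PEEPA-P5 against 92.3 ± 87.4 CPM, and Prap1 at 8.49 ± 3.69 against 2.99 ± 1.052 CPM. Apoa4, an enterocyte apolipoprotein, had 2.22 ± 3.34 against 37.8 ± 37.5 CPM. The intestinal transcription factor Cdx2 was at 3.19 ± 2.67 against 1.29 ± 0.69 CPM, Muc2 at 22.5 ± 22.5 against 7.83 ± 4.28 CPM and Tff3 at 37.4 ± 37.1 against 11.7 ± 4.90 CPM, and in none of these 3 were the groups separate. The lowest list mean of all 6 libraries was that of PEEPA-P5 1, at -0.40, the difference of the list means was 0.22 (exact permutation p = 0.4), and 2 of 3 numbered pairs were higher with PEEPA-P5. Cdx1 had at most 2 counts in any library and was not tested. The call was lost without PEEPA-P5 2 (median 0.54), without PEEPA-P5 3 (median 0.17) and without both libraries numbered 3 (median 0.21).

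Enteroendocrine genes fell, with 23 of 25 members lower and a median of -1.02 (camera adjusted p 0.0061, adjusted p = 0.814 with an estimated correlation). Ghrl, which encodes ghrelin, was at 108 ± 82.3 CPM with PEEPA-P5 against 690 ± 271 CPM, and Hdc, the histamine-forming enzyme, at 0.96 ± 0.50 against 7.76 ± 8.70 CPM. Isl1 and Ddc had log2 differences of -1.60 and 0.45. The antral hormone gene Gast was at 838 ± 721 against 1071 ± 871 CPM, with a log2 difference of -0.35 and a standard error of 1.28, and Sst at 49.7 ± 40.4 against 143 ± 109 CPM. The call was lost without PEEPA-P5 3 (median -0.13), without vehicle 1 (median -0.80) and with library totals as the only scaling (median -1.09), and without PEEPA-P5 1 the median was -1.72. The list means overlapped (exact permutation p = 0.3) and were lower with PEEPA-P5 in 3 of 3 numbered pairs, and without both libraries numbered 3 the list passed at -0.60. Without the block, the log2 difference of Gast was 0.31 without vehicle 1 and 0.21 without PEEPA-P5 3, while Gast was lower with PEEPA-P5 in 3 of 3 numbered pairs (log2 difference -0.70 with the block, edgeR adjusted p 0.364). Mki67, a marker of dividing cells, was at 131 ± 44.2 against 117 ± 40.5 CPM, and its log2 difference without the block was -0.06 without vehicle 3 and -0.01 without PEEPA-P5 2, while it was higher in 3 of 3 numbered pairs (0.16 with the block, edgeR adjusted p 0.494). The cell cycle list did not pass (camera adjusted p 0.589), but passed upward without vehicle 2 (median 0.24) and without PEEPA-P5 3 (median 0.28).

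Lists of the tissue under the epithelium passed camera downward, with PEEPA-P5 3 the lowest library in each. The list means of endothelium, fibroblasts and smooth muscle were lower with PEEPA-P5 in 3 of 3 numbered pairs, and those of macrophages in 2 of 3. The exact permutation p of the list means was 0.2 for endothelium, 0.4 for fibroblasts, 0.3 for smooth muscle and 0.7 for macrophages, for which PEEPA-P5 2 was the highest library, at 0.77. Endothelial genes fell, with 21 of 21 members lower and a median of -1.21 (camera adjusted p 2.1e-05, adjusted p = 0.814 with an estimated correlation). Tie1 was at 1.78 ± 1.13 CPM with PEEPA-P5 against 4.50 ± 1.07 CPM, Sox17 at 0.49 ± 0.08 against 1.26 ± 0.51 CPM, and Cdh5 and Vwf had log2 differences of -1.47 and -1.26. Without PEEPA-P5 3 the endothelial median was -0.49 and the list still passed. Fibroblast and matrix genes fell, with 31 of 33 members lower and a median of -1.049 (camera adjusted p 0.0015, adjusted p = 0.814 with an estimated correlation). Ccl11 was at 2.10 ± 0.98 against 6.00 ± 2.71 CPM, Fbln2 at 1.53 ± 1.12 against 5.04 ± 1.82 CPM, Mfap4 at 0.60 ± 0.49 against 2.75 ± 1.66 CPM and Serpinf1 at 0.42 ± 0.32 against 0.97 ± 0.43 CPM. Smooth muscle genes fell, with 19 of 23 members lower and a median of -1.06 (camera adjusted p 0.018, adjusted p = 0.814 with an estimated correlation). Kcnmb1, Hspb7 and Tpm1 had log2 differences of -1.20, -1.13 and 0.21. Macrophage and dendritic cell genes fell, with 19 of 20 members lower and a median of -0.87 (camera adjusted p 0.036, adjusted p = 0.814 with an estimated correlation). Among them Laptm5 and Aif1 had log2 differences of -0.70 and 0.72, Fcgr3, with 13.4% of its sequence shared with Fcgr2b, one of -0.77, and Itgam, with 67.2% of its sequence shared with a predicted gene, one of -1.053. Without PEEPA-P5 3 the fibroblast, smooth muscle and macrophage lists no longer passed, at medians of -0.10, -0.27 and -0.09. The smooth muscle and macrophage calls were also lost without vehicle 1, at -1.049 and -0.75, and without vehicle 2, at -0.89 and -0.75, and with library totals as the only scaling, at -1.14 and -0.95. Without PEEPA-P5 2 the fibroblast, smooth muscle and macrophage medians were -1.71, -1.71 and -1.48, and without both libraries numbered 3 the endothelial, fibroblast and smooth muscle lists passed, at -0.53, -0.39 and -0.48, and the macrophage list did not, at -0.35.

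PEEPA-P5 3 had the lowest mean of 11 of the 13 tested lists for cell types foreign to the gastric epithelium. It was also lowest for the parietal, chief, enteroendocrine, gland and neck mucous, tuft and antral stem cell lists, and highest for the pit list. Genes with a count numbered 14897 in PEEPA-P5 3, the fewest, against 15530 to 15959 in the other libraries. The first principal component of the 500 most variable genes held 68.1% of the variance. It set PEEPA-P5 3, at 58.3, apart from the rest, with PEEPA-P5 1 at 18.0, PEEPA-P5 2 at -7.80, vehicle 1 at -9.25, vehicle 2 at -28.7 and vehicle 3 at -30.6. The common biological coefficient of variation was 25.9%.

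**Figure D3:**
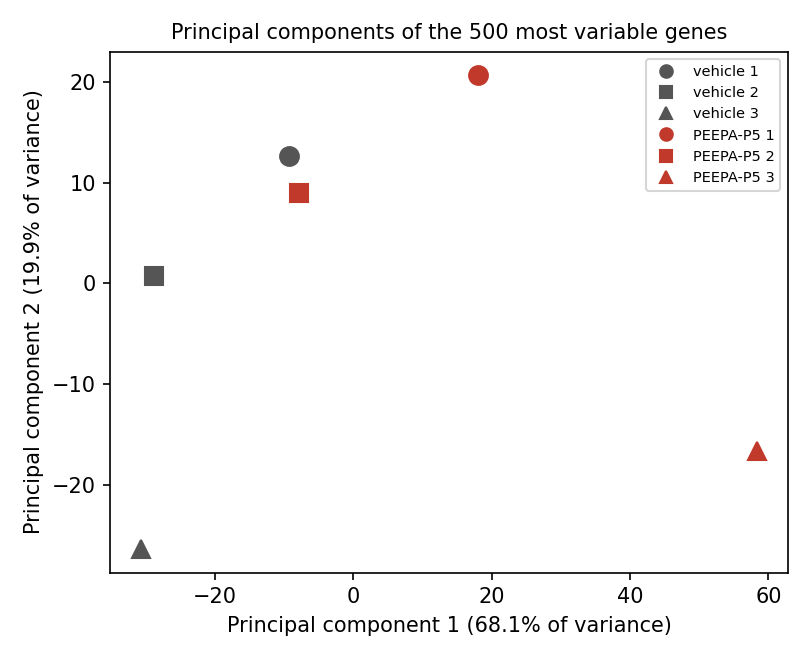
First and second principal components of log2 CPM of the 500 most variable genes (68.1% and 19.9% of the variance), each point a library of the vehicle (grey) or PEEPA-P5 (red) group with its number as the marker shape. PEEPA-P5 3 lies alone at 58.3 on the first component, and PEEPA-P5 2 at -7.80 lies beside vehicle 1 at -9.25.

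A further 6 lists passed with the replicate number as a block and not without it. With the block and an estimated correlation 0 of the 46 lists passed (smallest adjusted p = 0.694), and fry with the block called 0. They were oxidative phosphorylation (median 0.07, blocked adjusted p 0.031, unblocked 0.056), epithelial-mesenchymal transition (-0.76, blocked 0.0051, unblocked 0.056), immediate early genes (0.25, blocked 0.0499, unblocked 0.064), adipocytes (-0.49, blocked 0.0499, unblocked 0.068), Wnt targets (-0.46, blocked 0.041, unblocked 0.092) and the Notch pathway (-0.28, blocked 0.036, unblocked 0.0996), all by camera with the preset correlation. The lists of SPEM genes, which mark metaplastic mucous cells, antral stem and progenitor cells, tuft cells, DNA damage and p53 targets, NF-kB targets, type I interferon response, interferon gamma response, NRF2 response, heat shock response, glycolysis, fatty acid oxidation, xenobiotic metabolism, growth factors, mucosal defence, YAP targets, circadian clock and ribosomal proteins did not pass. Their camera adjusted p-values ran from 0.093 for heat shock to 0.935 for NF-kB targets. The remaining cell type lists, for skeletal muscle, enteric neurons and glia, B and plasma cells, mast cells and eosinophils, erythroid cells and hepatocytes, had adjusted p-values from 0.143 for hepatocytes to 0.935 for skeletal muscle. Median, mean and test differed in sign in 6 of these lists. The median was above 0 and the mean below it, with an upward camera direction, for ribosomal proteins, mucosal defence, xenobiotic metabolism and fatty acid oxidation, the median was below 0 and the mean above it with an upward direction for interferon gamma, and both were below 0 with an upward direction for glycolysis. Without vehicle 1 the type I interferon and interferon gamma lists passed upward, at medians of 0.70 and 0.46. Lists for interstitial cells of Cajal, T and NK cells and neutrophils had 4, 2 and 1 tested members and were not tested.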

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

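The fit without both libraries numbered 3, DESeq2 with the replicate block, and the blocked set tests with an estimated correlation or fry were chosen after the results had been seen, and the other alternatives before. Causes of the changes below were not tested. In edgeR with other scaling factors, other filters or the replicate block, in limma-voom and in limma-trend on TPM, 0 genes passed, as in edgeR itself, where 1576 had an unadjusted p under 0.05 (1788 with the block, 1533 in limma-voom, 1014 and 962 in limma-trend with pseudocounts of 1 and 0.1). DESeq2 called 110 genes, 39 higher and 71 lower, and with the replicate block 144, 63 higher and 81 lower. Of the 110, 106 were tested in edgeR, and all 106 had an unadjusted p under 0.05 there. With each library left out in turn, edgeR called between 0 and 1 genes higher and between 0 and 1 changed. None of the 84 named genes passed in edgeR, so keeping the side of the threshold means staying uncalled. Of 1569 alternative values, 1518 kept their direction and side and 47, all from DESeq2 without or with the block, newly passed the threshold. The other 4 turned direction: Gast at 0.31 without vehicle 1 and 0.21 without PEEPA-P5 3, and Mki67 at -0.060 without vehicle 3 and -0.0080 without PEEPA-P5 2, in a range up to 0.44 without vehicle 2. At this depth and group size, edgeR called 8% of simulated 1.5-fold changes, 32% of 2-fold and 86% of 4-fold changes. The 0 calls therefore do not show that small differences are absent. Genes were drawn independently in the simulation, without shifts shared by many genes of a library. It cannot say why larger differences were not called.

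Of the 46 lists tested, 15 passed camera, 0 passed with an estimated correlation, 0 with fry and 0 with fry mixed, and 0 with the replicate block and an estimated correlation or with fry and the block. These tests leave the medians of the 15 as they were, at -2.35 for parietal cells, -2.14 for chief cells, 0.30 for pit mucous cells, -1.02 for enteroendocrine cells, 0.51 for intestinal genes, 0.74 for squamous epithelium, -3.51 for exocrine pancreas, -1.049 for fibroblasts, -1.06 for smooth muscle, -1.21 for endothelium, -0.87 for macrophages, 0.27 for junctions and keratins, 0.33 for cholesterol synthesis, 0.15 for the unfolded protein response and 0.22 for apoptosis. The replicate block in camera gave 21 lists, with adipocytes (-0.49), Wnt targets (-0.46), Notch (-0.28), epithelial-mesenchymal transition (-0.76), oxidative phosphorylation (0.071) and immediate early genes (0.25) added, and changed no other call in camera or edgeR. With library totals as the only scaling, enteroendocrine cells (-1.09), smooth muscle (-1.14) and macrophages (-0.95) no longer passed and immediate early genes (0.17) did. Without both libraries numbered 3, 18 lists passed. Of the 15, intestinal genes (0.21), exocrine pancreas (-1.91), macrophages (-0.35), junctions and keratins (0.077) and apoptosis (0.10) no longer passed. The 8 lists added were enteric neurons (-0.37), cell cycle (0.091), interferon gamma (-0.38), Notch (-0.28), YAP targets (-0.30), oxidative phosphorylation (0.12), heat shock (0.27) and ribosomal proteins (0.052).

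With each library left out in turn, between 13 and 24 lists passed. Medians of lists whose call was lost in some of these fits ran from -1.72 to -0.13 for enteroendocrine cells, 0.17 to 0.65 for intestinal genes, -1.71 to -0.10 for fibroblasts, -1.71 to -0.27 for smooth muscle, -1.48 to -0.093 for macrophages, 0.12 to 0.17 for the unfolded protein response and 0.12 to 0.31 for apoptosis. Medians of lists that passed only in some of them ran from -0.78 to -0.022 for tuft cells, -0.99 to -0.27 for enteric neurons, -0.86 to -0.26 for adipocytes, -1.27 to 0.10 for mast cells and eosinophils, -1.24 to -0.020 for erythroid cells, -2.03 to -0.69 for hepatocytes, -0.16 to 0.28 for cell cycle, -0.38 to 0.70 for type I interferon, -0.20 to 0.46 for interferon gamma, -0.58 to 0.075 for Wnt targets, -0.48 to -0.13 for Notch, -0.44 to -0.14 for YAP targets, -1.16 to -0.019 for epithelial-mesenchymal transition, 0.0033 to 0.17 for oxidative phosphorylation, -0.0023 to 0.15 for NRF2, 0.029 to 0.38 for immediate early genes, 0.17 to 0.25 for heat shock and -0.39 to -0.0091 for the circadian clock. With 1 library left out, the lists added were both interferon lists without vehicle 1, cell cycle and immediate early genes without vehicle 2, and tuft cells, enteric neurons, adipocytes, erythroid cells, Wnt, YAP, epithelial-mesenchymal transition, oxidative phosphorylation, NRF2 and heat shock without vehicle 3. They were hepatocytes, Wnt, epithelial-mesenchymal transition, oxidative phosphorylation and immediate early genes without PEEPA-P5 1, and tuft cells, adipocytes, mast cells, hepatocytes, Wnt, YAP, epithelial-mesenchymal transition, oxidative phosphorylation and NRF2 without PEEPA-P5 2. Without PEEPA-P5 3 they were cell cycle, Notch, heat shock and the circadian clock.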

Other observations

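The tests of technical explanations and the comparison of synthesis branches in this part were chosen after the results had been seen, and so was the comparison of splits that part all pairs. The genes named here that the report does not name were picked after their values were seen.

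Clca1, secreted by goblet cells, was at 3129, 4810 and 4576 CPM in the PEEPA-P5 libraries and at 2485, 1488 and 344 CPM in vehicle 1, 2 and 3. Fcgbp, an IgG-Fc binding mucus protein, was at 4280, 5230 and 5409 CPM with PEEPA-P5 and at 4834, 935 and 684 CPM with vehicle. Zg16 was at 398, 630 and 245 CPM against 190, 65.3 and 21.7 CPM. The predicted gene Gm42048 was at 129, 167 and 124 CPM against 99.1, 4.16 and 2.95 CPM. In edgeR their unadjusted p-values were 0.061, 0.162, 0.035 and 0.174, and none passed after adjustment. Vehicle 1 lay within the PEEPA-P5 range in Fcgbp and below it in Gm42048.

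Among the SPEM genes, Wfdc2 had a log2 difference of 0.64 with a standard error of 0.15 and Ceacam10 one of -1.78 with a standard error of 0.35. These 2 passed when adjusted over the list alone, in opposite directions, and the list had 12 members higher and 9 lower. Amotl2, a YAP target, was at 6.57 ± 1.14 CPM with PEEPA-P5 against 14.3 ± 3.12 CPM and was the 1 member of its list to pass when adjusted over the list alone. The complement gene C3 was at 1.504 ± 0.86 against 6.62 ± 3.39 CPM. Lpl and the glucose transporter gene Slc2a4 were at 7.46 ± 7.66 against 53.1 ± 40.0 CPM and at 1.56 ± 1.63 against 14.4 ± 10.9 CPM. Of 6 tested erythroid genes, 3 passed when adjusted over the list alone, all lower with PEEPA-P5 (smallest edgeR p so adjusted 0.049). The erythroid list did not pass camera (adjusted p 0.261), and its means overlapped between groups (exact permutation p = 0.4). Type I interferon genes varied between libraries of 1 group, with list means of 1.31, -0.99 and -0.51 in vehicle 1, 2 and 3 and of 0.59, -0.60 and 0.19 in PEEPA-P5 1, 2 and 3, in log2 units from the mean of the 6. Oasl2 was at 148, 8.09 and 13.1 CPM in the vehicle libraries. Gast was at 1859, 1219 and 135 CPM in vehicle 1, 2 and 3 and at 1460, 1004 and 48.0 CPM in PEEPA-P5 1, 2 and 3.

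Acid-gland genes were lower with PEEPA-P5, and lower sequencing depth is argued against, as the mean total of the PEEPA-P5 libraries was 0.998 of the vehicle mean. A different share of acid-gland mucosa in each library is a candidate explanation. Within the groups, deviations of the parietal and chief list means moved together (Pearson r = 0.99, Spearman rho = 1, exact permutation p = 0.0278 for each, the smallest that 36 within-group permutations give, adjusted 0.0556 over the 2 relations tested, n = 6), and r was 0.963 without vehicle 3 and PEEPA-P5 2. Any joint change of both cell types would give this correlation too, so it cannot single out the share of mucosa in a dissected piece. Less acid-gland and more antral mucosa would leave the antral hormone gene Gast high. In vehicle 1, 2 and 3 Gast was at 1859, 1219 and 135 CPM, at parietal means of 0.24, 1.36 and 2.27. That order goes with this explanation. In PEEPA-P5 1 and 2 Gast was at 1460 and 1004 CPM, at parietal means of -1.70 and 0.23. PEEPA-P5 3, with the lowest parietal and chief means, also had the lowest Gast (48.0 CPM), which goes against this explanation in that library. Its enteroendocrine mean was the lowest too (-2.33), but that list is not limited to antral cells and counts neither for nor against it. Gast was low in both libraries numbered 3, so it does not settle the question. An effect of PEEPA-P5 on these cells stays open as untested, because the share of acid-gland mucosa in each dissected piece is not known.

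Surface and squamous-type genes were higher with PEEPA-P5. Forestomach epithelium in the PEEPA-P5 libraries is argued against, as the larger of the mean CPM values of Krt5 and Krt14 there was 0.0395, while Krt13 was at 7.91 CPM. Whether a larger share of pit cells alone would do could not be told. The squamous median exceeded the pit median by 0.44 and, with each library left out in turn, by at least 0.282. Different gene lists need not shift by the same amount when the share of a cell type changes. A change within the surface cells, whether from PEEPA-P5 or from where the tissue was taken, may remain, and was not tested.

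Cholesterol synthesis genes were higher with PEEPA-P5, with 23 of 23 sterol genes higher (median log2 difference 0.36, groups separate in 9, against 10% by chance and 20.4% of all tested genes) and 11 of 13 genes of fatty acids and other steps (median 0.19, separate in 1). A larger share of epithelium and collection at another time of day could not be told apart from an effect of PEEPA-P5. For the first, within-group deviations of the cholesterol and junction list means gave Pearson r = -0.531 (exact permutation p = 0.472, adjusted 0.472, n = 6) and Spearman rho = -0.6 (exact permutation p = 0.361, adjusted 0.361), and r was 0.763 without PEEPA-P5 1 and PEEPA-P5 3, so the relation rests on those libraries. For the second, 1 of 19 clock genes had an unadjusted p under 0.05, but the 95% intervals were wide, from -1.74 to 1.02 for Dbp on the log2 scale.

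With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In edgeR, 10 of the 10 splits gave as many genes past the adjusted threshold, as the real count was 0 and the highest of the others 0. At an unadjusted p under 0.05 the real split gave 1576 genes and the highest other 1092, so that 1 split reached the real count. In DESeq2 the real split gave 110 genes and the highest other 93, again 1 split. For lists, 6 of the 10 splits gave at least the 15 of the real one, and the highest other gave 20. The split with the 93 genes set vehicle 1, PEEPA-P5 1 and PEEPA-P5 3 against the rest. Of the 4 splits that part all 3 pairs of numbers, the others gave at most 311 genes at an unadjusted p under 0.05, at most 1 gene in DESeq2 and up to 20 lists. The pairing was taken from these same data, and this choice leaves out the split with 1092 genes and 93 in DESeq2. The smaller set of splits therefore cannot say how unusual the real one is.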
